A study of Danio rerio with 8 samples.

How the data were processed

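RNA was taken from whole bodies of 5-week-old pex2 mutant larvae and their wild-type siblings with a Maxwell RSC kit, and the fish were genotyped on tail fin DNA, per the labels' protocols. Equal amounts from 3 larvae made each pool, and the 4 pools per genotype were labelled with Cy3 and hybridised to one-colour Agilent arrays, per the labels. The sex of the larvae is not given in the sources used here. Whether larvae of different pools came from separate clutches is not given in the sources used here, so p-values measure the spread between pools.

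The deposited scanner files hold 1 intensity per spot, background-corrected by Agilent Feature Extraction (named in the submitters' processing notes; version 10.7.3.1 and protocol GE1_107_Sep09 per the file headers). The deposited series matrix holds log2 values. They matched the scanner intensity after log2, scaling to the 75th percentile and centring of each probe on its median over the 8 arrays. Per array, 99.4% to 99.5% of values lay within 0.01. Its column medians lay between -0.09 and 0.17. It was used as an alternative, and its scale, centring and direction were known from this match.

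All 8 arrays lay on 1 slide and were scanned once, together, per the file headers, each row of the slide holding 2 pools of each genotype, so neither slide nor scan was a batch. Of 61657 spots that were not controls, the 1099 outlier spots summed over the 8 arrays were left out, spots of a probe were averaged, and no spot was saturated. Log2 intensity minus the 75th percentile of each array was used. Of 39749 probes, 29937 were well above background on at least 4 of 8 arrays and were kept. Each probe carries 1 RefSeq accession and no gene name. The table of the GRCz12tu assembly named 61.8% of probes, 97.2% of those with curated mRNA accessions and 50.0% of those with predicted ones. The array's grid names the older build danRer7, so no coordinates are given. It pairs pex2 with 1 accession, which 0 probes carry, so the planned check of the mutated gene was not made.

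Genotypes were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes, two-sided, and Benjamini-Hochberg adjustment over all probes kept. A gene was represented by its brightest probe; 2334 genes had more than 1 kept probe and 50 had probes called in opposite directions. Where no array of a genotype was well above background, the difference is a bound, the bright genotype's mean against the dim one's mean of, per array, the higher of its own value and the lowest value well above background. Bounds were computed with the main background correction alone. The 34 gene lists, with 909 measured genes, and the rule for named genes were fixed before the data were examined. The rule names the 10 largest rises and falls past the threshold with no overlap of genotypes, a signal on all 4 arrays of 1 genotype and no clone or locus name, the members of 3 peroxisomal lists, up to 4 genes of smallest adjusted p in other lists, and 5 genes of the insulin-like growth factor axis. Peroxisomal members that did not pass are given as counts. Of all the genes that the rule names, 1 other gene is not reported here. Lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 and with an estimated one, and with fry; 48 missing values were set to the genotype's mean for these. Fry's directional test, which does not compare a list with other genes, passed 23 lists and its mixed test 33.

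The fit was tested on simulated arrays of 17264 genes, 200 of them changed, with 4 arrays per genotype. It recovered 20.5% of 1.5-fold changes, 67.0% of 2-fold, 88.0% of 4-fold and 98.0% of 8-fold changes, with 3 to 11 false calls. The simulated errors were independent between genes, and in the real data 9951 genes passed. These rates and counts of false calls therefore do not carry over to the real comparison. Alternatives were normexp background correction with an offset of 50, which used spot medians in place of means, quantile and median scaling, other filters on dim probes, outlier spots kept, the deposited table, other settings of the fit, a replicate or slide-row block, a test against a 1.2-fold change, a threshold of 0.01, the mean of all probes of a gene, and each array left out in turn. An exact permutation of the arrays for each list was added after seeing the data.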

Results

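Gene expression was measured in whole bodies of zebrafish larvae at 5 weeks of age, in a model of Zellweger syndrome made by mutating pex2. Pex2 is a membrane protein of the peroxisome, the organelle that shortens very long chain fatty acids and makes ether lipids, and takes part in importing its enzymes. Each of the 8 samples was a pool of RNA from 3 larvae, hybridised to its own one-colour array. There were 4 pools of pex2 mutants and 4 pools of their wild-type siblings. The 75th percentile of intensity was 699 ± 108 on the sibling arrays and 476 ± 24.9 on the mutant arrays (SD, n = 4 each, exact two-sided permutation p = 0.0286, the smallest that 4 against 4 can give). The 100 brightest probes held 29.3% ± 1.73 of the signal on the sibling arrays and 35.4% ± 1.74 on the mutant arrays (SD, n = 4 each, exact permutation p = 0.0286). Between 72.7% and 76.3% of probes were well above background on 7 arrays, and 67.3% on mutant replicate 4. The number of arrays limits the precision of every value. No probe could be named pex2, so the transcript of the mutated gene was not used to check the labels.

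The comparison of mutants with siblings asks which transcripts differ in larvae that lack a working pex2 gene. In the mutant pools, most measured genes of the lens, bone and cartilage, intestine, exocrine pancreas, lymphocyte, acute phase and oocyte lists were lower, and most of the neuron list were higher. Growth hormone (gh1) was 8.70-fold lower (log2 difference -3.12 ± 0.16 SE, n = 4 pools per genotype, adjusted p = 3.13e-05), and was well above background on 1 of the 4 mutant arrays and on all 4 sibling arrays. With normexp background correction its difference was -1.21, and those of 33 of 168 called genes that are named shrank by over 1.5 times. The stress-induced circulating factor gdf15 was 11.5-fold higher (3.53 ± 0.25, adjusted p = 5.37e-05). Genes of the peroxisome itself went in both directions. Values after gene names are log2 differences, mutant minus sibling, ± the moderated standard error, with adjusted p from limma. Counts within a list were the same adjusted over the list alone, except where given.

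Of 17264 named genes tested, 9951 (57.6%) passed an adjusted p of 0.05, 5156 higher and 4795 lower in the mutants. Counts within a list are to be read against this share, and the 3 peroxisomal lists, among others, fell below it. A change of at least 2-fold was found in 1226 higher and 2138 lower genes. Of 9949 probes without a gene name, 4235 were higher and 1804 lower, with 1317 higher and 921 lower by at least 2-fold. Over all 29937 probes 10387 were higher and 7147 lower. The 2 genotypes did not overlap in 9429 genes, 54.6% of those tested, where chance gives 2.86%. The first principal component held 69.0% of the variance and parted the genotypes, and the second, with 14.0%, parted mutant replicate 4 from mutant replicate 1. Correlations lay between 0.981 and 0.992 among sibling arrays, between 0.935 and 0.980 among mutant arrays, and between 0.861 and 0.929 across genotypes.

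**Figure D1:**
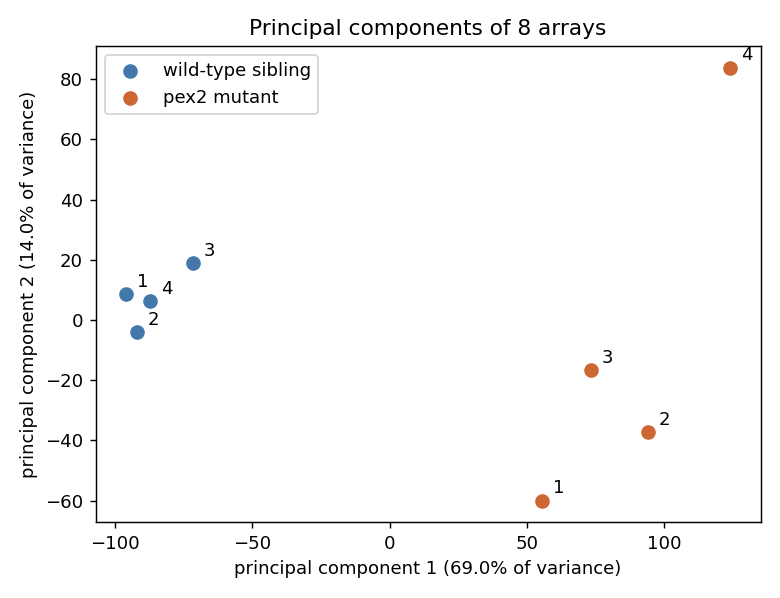
First against second principal component of log2 values, in arbitrary units, for 4 sibling and 4 mutant pools, each point 1 array numbered by replicate. The genotypes lie apart on the first axis, and mutant replicate 4 lies at 83.8 on the second against -60.0 for mutant replicate 1.

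Among the 10 largest falls were the lens crystallin crygm6 (-7.53 ± 0.38), the haem-binding plasma protein hemopexin hpxa (-7.09 ± 0.96), the fast muscle myosin myhc4 (-5.86 ± 0.79) and the elastase cela1.5 (-5.77 ± 0.63). Egg-coat genes among them were zpcx (-5.99 ± 1.22), zp3e (-5.87 ± 1.26) and zp2.3 (-5.75 ± 2.04). The other 3 were cth1 (-6.32 ± 1.33), qdprb.3 (-6.01 ± 1.7) and hist1h2a6 (-6.05 ± 1.74). The call of zp2.3 was lost without sibling replicate 1, 2, 3 or 4 or without mutant replicate 2 or 3 (adjusted p between 0.0503 and 0.0813), and its value was -3.47 without mutant replicate 4. Without mutant replicate 4 the values were -5.01 for zpcx, -4.64 for zp3e, -5.11 for cth1, -4.26 for qdprb.3 and -4.29 for hist1h2a6. Without mutant replicate 1 they were -7.15, -7.00, -7.55, -7.37 and -7.44, and that of zp2.3 was -7.09. That of cela1.5 was -5.14 without mutant replicate 1, and that of hpxa -6.39 without mutant replicate 2 and -7.89 without mutant replicate 3. The call of zp2.3 was also lost with a trended, robust fit and with no filter on dim probes. All 10 were well above background on every sibling array and on 1 to 3 of the mutant arrays. Among the 10 largest rises, gdf15 (3.53 ± 0.25), angptl6 (2.62 ± 0.13), the phospholipase pla1a (3.16 ± 0.36) and the transcriptional repressor nfil3-2 (2.56 ± 0.18) were well above background on all 8 arrays. The gene kctd3 (3.55 ± 0.87) was so on 2 sibling arrays and all mutant arrays, and its value was 4.29 without sibling replicate 2. The other 5 were not well above background on any sibling array, so only a bound can be given. It was at least 9.59-fold higher for ggact.1 (adjusted p = 5.07e-05), at least 6.88-fold for ggact.2 (adjusted p = 7.27e-05). It was at least 8.46-fold for pla2g3 (adjusted p = 4.12e-04), at least 8.12-fold for mhc2d8.35b2 (adjusted p = 0.00885) and at least 4.59-fold for cherp (adjusted p = 1.63e-04). The bound for mhc2d8.35b2 was 3.79-fold without mutant replicate 4. These bounds hold for the main background correction and not for every setting. Over all settings the lowest log2 differences were 2.03 for ggact.1, 1.78 for ggact.2, 1.53 for pla2g3, 1.83 for mhc2d8.35b2 and 1.39 for cherp. Each is smaller than the bound of its gene.

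Of 16 measured genes for peroxisome biogenesis, 4 were higher, 3 lower and 9 did not pass (4 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.821). The membrane protein pxmp4 (1.00 ± 0.15, adjusted p = 7.79e-04) rose most, with pex11g (0.56 ± 0.12), pex14 (0.46 ± 0.09) and pex5 (0.33 ± 0.09). The 3 that fell were pex10 (-0.57 ± 0.12), pex6 (-0.44 ± 0.13) and pex26 (-0.26 ± 0.10). Of 24 genes for peroxisomal fatty acid oxidation, 4 were higher and 3 lower (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.799). The bifunctional enzyme ehhadh (-1.35 ± 0.28, adjusted p = 0.00360) and the thioesterase acot8 (-1.08 ± 0.38) fell, as did cratb (-0.54 ± 0.20). The 4 that rose were acoxl (0.65 ± 0.21), crot (0.51 ± 0.19), crata (0.43 ± 0.12) and acbd5a (0.40 ± 0.08). This list had a median of 0.07 and a mean of -0.02, and camera gave it an upward direction. Of 26 other peroxisomal enzymes and ether lipid genes, 7 were higher and 3 lower (6 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.490). The glyoxylate enzymes agxtb (1.36 ± 0.19), hao1 (1.2 ± 0.15) and agxta (0.57 ± 0.13) rose. So did dao.1 (0.92 ± 0.10), uraha (0.90 ± 0.17), lonp2 (0.44 ± 0.11) and nudt12 (0.25 ± 0.09). Relative to the 8 arrays, the mean of the biogenesis list was between 0.01 and 0.09 in the mutant pools and between -0.06 and -0.02 in the sibling pools. The list's own mean difference was 0.08, and measured against the mean of all genes it was 0.20 (exact permutation p = 0.0286, adjusted p = 0.0511). The directional test of fry, which compares with no other genes, gave an adjusted p of 0.0418 for this list, 0.0272 for the other enzymes and 0.579 for fatty acid oxidation. The 3 lower enzymes were prdx5 (-0.44 ± 0.10), dao.2 (-0.48 ± 0.15) and ddo (-0.78 ± 0.29), the last well above background on 1 mutant array. The call of pex26 was lost without sibling replicate 1, 2, 3 or 4 or without mutant replicate 1, 2 or 3 (adjusted p between 0.0543 and 0.125), that of nudt12 without sibling replicate 1, 2, 3 or 4 or without mutant replicate 1, 2 or 3 (adjusted p between 0.0534 and 0.0995), and that of cratb without sibling replicate 1, 2, 3 or 4 or without mutant replicate 2 or 3 (adjusted p between 0.0615 and 0.107). That of crot was lost without sibling replicate 1, 2 or 4 or without mutant replicate 1, 3 or 4 (adjusted p between 0.0701 and 0.112), that of acoxl without sibling replicate 1, 2 or 4 or without mutant replicate 3 (adjusted p between 0.0578 and 0.0711), and that of ddo without sibling replicate 1, 3 or 4 or without mutant replicate 1, 2 or 4 (adjusted p between 0.0726 and 0.115). That of dao.2 was lost without sibling replicate 3 or 4 or without mutant replicate 3 (adjusted p between 0.0580 and 0.0678), and that of acot8 without sibling replicate 4 or without mutant replicate 1, 2, 3 or 4 (adjusted p between 0.0545 and 0.0861), with a value of -0.66 without sibling replicate 3. The calls of pex10, pex6, pex26, cratb and acot8 were also lost with normexp background correction, that of pex10 with outlier spots kept, and those of pex26, cratb, crot, nudt12, ddo and acot8 with no filter on dim probes. Those of pex26, cratb and nudt12 were lost with quantile scaling, and those of pex26, cratb and crot with median scaling. Array weights ended those of ddo and nudt12, and a trended, robust fit those of cratb and ddo. With the slide row as a block those of pex26, cratb, crot and nudt12 were lost.

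Genes of growth and fasting are given next. In the growth hormone and insulin-like growth factor list 7 of 20 genes were higher and 5 lower (camera adjusted p = 0.824, median -0.04, mean 0.08). This was near the 57.6% of all named genes that passed. The binding proteins igfbp1a and igfbp1b, which restrain insulin-like growth factors and are induced by fasting, were 4.39-fold (2.13 ± 0.36) and 3.18-fold (1.67 ± 0.40) higher. The signalling inhibitor socs2 (1.32 ± 0.15) and the receptor igf1rb (0.85 ± 0.15) rose. For the ligands, igf2a was higher (0.74 ± 0.14), igf2b lower (-0.55 ± 0.10), and igf1 did not pass (-0.18 ± 0.25, adjusted p = 0.567). Of 21 fasting and muscle atrophy genes, 11 were higher and 0 lower (10 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.0114, adjusted p = 0.646 with an estimated correlation). Among them were irs2a (1.46 ± 0.18) and ppargc1a (1.11 ± 0.11). The forkhead factors foxo3a (1.00 ± 0.08) and foxo3b (0.94 ± 0.10) rose too.

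Liver transcripts were higher in 17 of 33 cases and lower in 3 (camera adjusted p = 0.00727, adjusted p = 0.646 with an estimated correlation). The clotting factors f9b (1.63 ± 0.14) and fga (1.5 ± 0.19) rose. So did the plasma proteins itih2 (0.97 ± 0.12) and vtna (0.96 ± 0.10). In amino acid catabolism and the urea cycle 17 of 38 were higher and 5 lower (camera adjusted p = 0.132). The enzymes mat1a (1.19 ± 0.14), cbsa (0.90 ± 0.11) and fah (0.79 ± 0.11) rose. The enzyme asl (-0.70 ± 0.10) fell. Of 16 bile acid genes 5 were higher and 7 lower (camera adjusted p = 0.824). The transporters slc51a (1.75 ± 0.16) and slco1d1 (1.71 ± 0.10) rose. The ileal bile acid carrier slc10a2 (-3.13 ± 0.37) and the transporter abcb4 (-1.84 ± 0.22) fell. Fatty acid synthesis and desaturation had 11 higher and 2 lower of 18 (camera adjusted p = 0.0813). This list passed without mutant replicate 2 (adjusted p 0.0347). The desaturase scdb (1.34 ± 0.10) and acacb (0.91 ± 0.15) rose. The elongases elovl1a (-1.63 ± 0.17) and elovl7a (-1.30 ± 0.18) fell. Mitochondrial fatty acid oxidation had 3 higher and 0 lower of 20 (camera adjusted p = 0.767). These were cpt1ab (1.18 ± 0.16), cpt1aa (0.72 ± 0.19) and acaa2 (0.59 ± 0.12). Cholesterol synthesis had 3 higher and 1 lower of 23 (2 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.142). This list passed without mutant replicate 2 or 3 (adjusted p 0.00455 and 0.0483). Relative to the 8 arrays, its mean was 1.16 and 1.23 in mutant replicates 1 and 4. It was -0.82 and -0.27 in mutant replicates 2 and 3, and -0.54 to -0.08 in the sibling pools. The mutant pools were thus split, and the exact permutation p against all genes was 0.314. The receptor ldlra (1.46 ± 0.24) stard4 (0.62 ± 0.17) and insig1 (0.60 ± 0.20) rose, with the call of insig1 lost without sibling replicate 2 or 4 or without mutant replicate 4 (adjusted p between 0.0530 and 0.0760), and srebf2 (-0.94 ± 0.22) fell, a call lost with quantile scaling. Gluconeogenesis and glycogen genes were higher in 4 of 17 and lower in 0 (3 higher and 0 lower adjusted over the list alone; camera adjusted p = 0.767). They were g6pc1a.1 (0.74 ± 0.18), pcxa (0.55 ± 0.14), pygmb (0.58 ± 0.08) and ugp2a (0.75 ± 0.24). The call of ugp2a was lost without sibling replicate 1, 2 or 4 or without mutant replicate 2 or 3 (adjusted p between 0.0577 and 0.0727). Adipose and lipid storage genes were split, 7 higher and 7 lower of 18 (7 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.767). The lipases pnpla2 (2.03 ± 0.32) and lpla (1.44 ± 0.14) rose. Both cebpa (-1.58 ± 0.19) and cidea (-0.57 ± 0.09) fell, and both calls were lost with normexp. On the mutant arrays cebpa was well above background on 2.

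**Figure D2:**
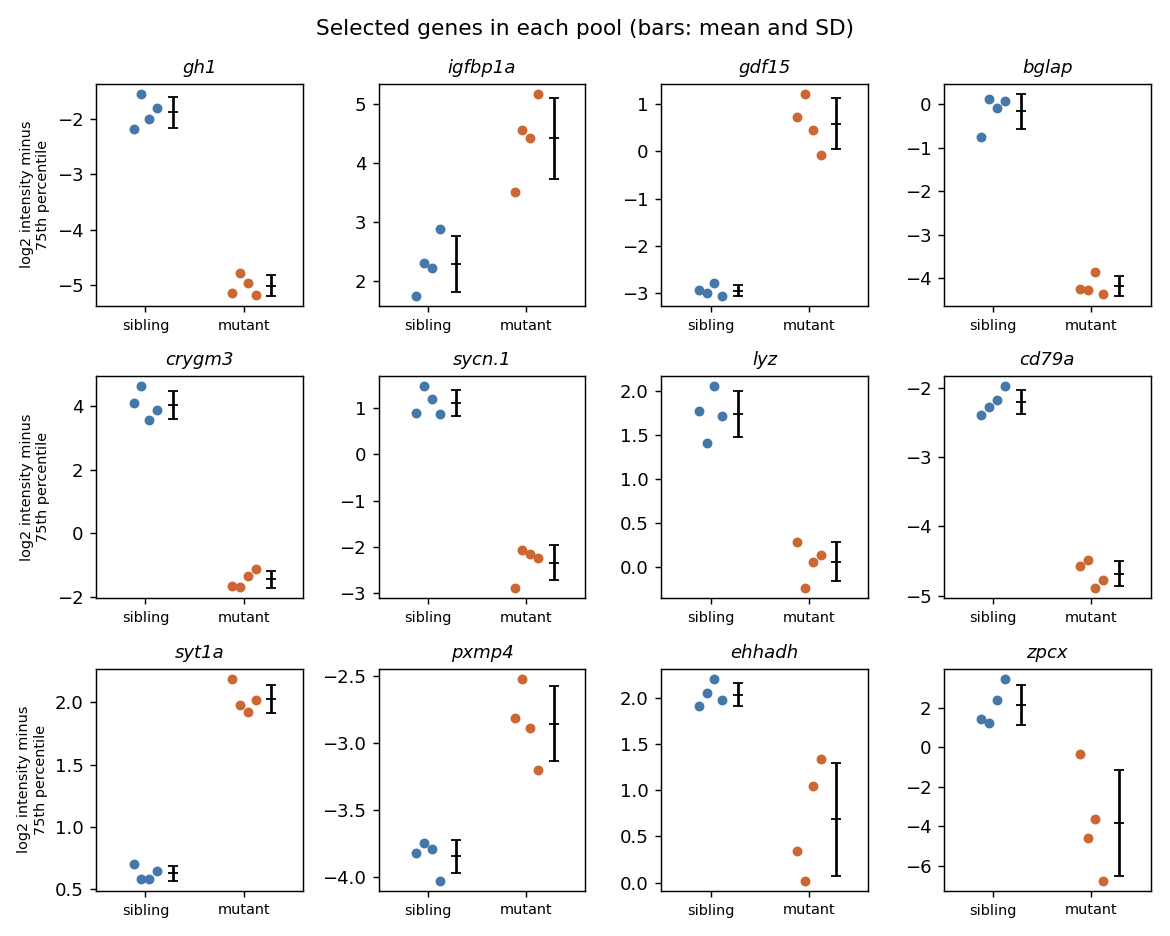
Log2 intensity minus the 75th percentile of its array for 12 genes, each point 1 pool, with bars for the mean and SD of 4 pools per genotype. The sibling and mutant pools of gh1, bglap, crygm3 and gdf15 do not overlap.

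Of 36 lens genes, 33 were lower and 1 higher (camera adjusted p = 8.17e-11, adjusted p = 0.468 with an estimated correlation). The crystallins crygm3, crygm5, crygmxl1 and crygn1 were 45.0-fold (-5.49 ± 0.24), 9.41-fold (-3.24 ± 0.21), 7.65-fold (-2.94 ± 0.13) and 4.46-fold (-2.16 ± 0.13) lower. Probes of such similar genes may read each other's RNA. Of 26 bone and cartilage genes 21 were lower and 0 higher (camera adjusted p = 1.31e-06, adjusted p = 0.468 with an estimated correlation). The osteoblast genes bglap, spp1 and ifitm5 fell, by 16.1-fold for bglap (-4.01 ± 0.21) and 8.73-fold for spp1 (-3.13 ± 0.20). On the mutant arrays bglap was well above background on 3. For ifitm5 the log2 difference was -3.46 ± 0.23. The collagen col10a1a was 15.5-fold lower (-3.95 ± 0.27). Skeletal muscle genes were lower in 8 and higher in 3 of 37 (camera adjusted p = 0.0810). This list passed without mutant replicate 1, 2 or 3 (adjusted p between 0.0204 and 0.0370), but not without mutant replicate 4. It also passed with normexp (adjusted p 0.0103) and with no filter (adjusted p 0.0299). Relative to the 8 arrays, its mean was -1.32 in mutant replicate 4. In the other mutant pools it was -0.05 to 0.17, and in the sibling pools 0.11 to 0.46. Over all settings the list's mean difference lay between -0.77 and -0.28, against -0.61 in the main one. The troponins tnni2a.1 (-2.97 ± 0.20) and tnni2b.1 (-2.03 ± 0.13) fell. So did desmb (-2.44 ± 0.32), well above background on 2 mutant arrays, and tpm2 (-1.45 ± 0.26).

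In the gut, 23 of 29 intestinal epithelium genes were lower and 1 higher (1 higher and 25 lower adjusted over the list alone; camera adjusted p = 5.27e-06, adjusted p = 0.646 with an estimated correlation). The amino acid transporter slc6a19b (-2.91 ± 0.30), the brush-border protease mep1a.1 (-2.75 ± 0.32) and sult1st1 (-0.80 ± 0.10) fell. The related mep1a.2 was not well above background on any mutant array and was at least 2.22-fold lower (adjusted p = 5.47e-05). Over all settings its smallest log2 difference was -0.33, a smaller fall than that bound. Exocrine pancreas genes were lower in 17 of 30 and higher in 0 (0 higher and 18 lower adjusted over the list alone; camera adjusted p = 3.55e-05, adjusted p = 0.646 with an estimated correlation). The zymogen granule gene sycn.1 (-3.44 ± 0.21) fell. So did the elastase cela1.2 (-3.22 ± 0.37).

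In the list of acute phase, neutrophil and inflammation genes 19 of 25 were lower and 2 higher (2 higher and 21 lower adjusted over the list alone; camera adjusted p = 1.06e-05, adjusted p = 0.567 with an estimated correlation). The lysozyme lyz (-1.68 ± 0.16), the protease mmp9 (-2.16 ± 0.19) and s100a10b (-1.54 ± 0.09) fell. The protease mmp13b, at background on the mutant arrays, was at least 1.76-fold lower (adjusted p = 4.53e-05). Over all settings its smallest log2 difference was -0.24, a smaller fall than that bound. Lymphocyte genes fell in 13 of 17 and rose in 1 (camera adjusted p = 1.21e-04, adjusted p = 0.567 with an estimated correlation). The B cell gene cd79a (-2.47 ± 0.13) fell. T cell genes that fell were cd4-1 (-2.13 ± 0.21), zap70 (-1.80 ± 0.16) and il7r (-1.66 ± 0.14). Of these il7r was well above background on 1 mutant array, and its difference was -0.35 with normexp. The B cell gene cd79a was so on 3 mutant arrays. Over all settings the smallest log2 differences were -0.91 for cd79a, -1 for cd4-1 and -0.90 for zap70. The mean of the lymphocyte list lay between -1.42 and -0.47 over all settings, against -1.35 in the main one. Macrophage and dendritic cell genes fell in 13 of 21 and rose in 2 (camera adjusted p = 0.00994, adjusted p = 0.646 with an estimated correlation). Both mpeg1.2 (-2.05 ± 0.24) and cd74b (-1.62 ± 0.18) fell, and havcr1 (0.65 ± 0.12) rose. The chemokine ccl34a.4, at background on the mutant arrays, was at least 2.02-fold lower (adjusted p = 7.24e-04), a call lost with normexp. Interferon response genes were lower in 9 and higher in 2 of 23 (camera adjusted p = 0.0414, adjusted p = 0.646 with an estimated correlation). The antigen-processing genes psmb8a (-2.24 ± 0.19), psmb9a (-1.83 ± 0.17) and tap1 (-0.80 ± 0.09) fell. So did gbp2 (-0.90 ± 0.10). The interferon call was lost without sibling replicate 1 or 3 or without mutant replicate 4 (adjusted p between 0.0568 and 0.115), and the mean difference of -0.32 was -0.13 without sibling replicate 3. It was also lost with array weights (adjusted p 0.118). Erythrocyte genes were lower in 10 and higher in 2 of 18 (camera adjusted p = 0.0532). This list passed without sibling replicate 2 or 4 or without mutant replicate 2, 3 or 4 (adjusted p between 0.0218 and 0.0461). It also passed with normexp (adjusted p 0.0154) and with no filter on dim probes (adjusted p 0.0212). The factor gata1a (-2.32 ± 0.32) and the anion exchanger slc4a1a (-1.95 ± 0.44) fell. So did cahz (-1.17 ± 0.25) and blvrb (-0.89 ± 0.15). On the mutant arrays gata1a was well above background on 2.

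Of 32 neuron genes 25 were higher and 2 lower (camera adjusted p = 4.45e-06, adjusted p = 0.646 with an estimated correlation). The synaptic vesicle genes syt1a (1.4 ± 0.09) and sv2a (1.06 ± 0.10) rose. So did the inhibitory neuron genes gad1b (1.47 ± 0.10) and slc32a1 (1.03 ± 0.09). Photoreceptor genes were higher in 17 and lower in 1 of 44 (camera adjusted p = 0.0133, adjusted p = 0.646 with an estimated correlation). This call was lost without mutant replicate 3 (adjusted p 0.0581), and with normexp (adjusted p 0.0720). Examples were cnga3a (1.46 ± 0.18), gucy2d (1.25 ± 0.14), gnb3a (1.07 ± 0.11) and prph2b (0.92 ± 0.11), with cnga3a well above background on 3 sibling arrays. Glia and myelin genes were split, 4 higher and 3 lower of 14 (camera adjusted p = 0.749). The glutamate transporter slc1a2b (1.06 ± 0.11), the glutamine synthetase glula (0.58 ± 0.12) and the myelin gene mag (0.56 ± 0.12) rose, and the myelin gene mbpb (-1.07 ± 0.09) fell. The glia list's mean difference was 0.16, and against all genes it was 0.28 (exact permutation p = 0.0286, adjusted p = 0.0511). Circadian clock genes were higher in 17 and lower in 2 of 34 (camera adjusted p = 0.00727, adjusted p = 0.646 with an estimated correlation). Examples were rorcb (2.23 ± 0.30), nfil3-5 (1.88 ± 0.19), npas2 (1.6 ± 0.21) and cry3b (1.37 ± 0.18), with npas2 well above background on 2 sibling arrays.

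Stress and organelle genes varied by list. Endoplasmic reticulum stress genes were higher in 6 and lower in 3 of 39 (camera adjusted p = 0.662). Both ddit3 (1.14 ± 0.12) and phgdh (1.01 ± 0.12) rose, and sesn2 (-0.80 ± 0.12) fell. Heat shock genes were lower in 10 and higher in 1 of 26 (1 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.0284, adjusted p = 0.646 with an estimated correlation). This call was lost without mutant replicate 1 or 2 (adjusted p 0.0578 and 0.0538), and with array weights (adjusted p 0.0633). The chaperones serpinh1b (-2.06 ± 0.44), hspb1 (-1.76 ± 0.23) and dnajb1b (-1.36 ± 0.15) fell, and hspb8 (1.13 ± 0.18) rose. Oxidative stress genes were split, 10 higher and 9 lower of 29 (11 higher and 10 lower adjusted over the list alone; camera adjusted p = 0.894; median 0.06, mean -0.11). The detoxifying genes gstp1.1 (-2.47 ± 0.18), gstp1.2 (-0.87 ± 0.10) and hmox1b (-1.15 ± 0.13) fell. The probes of nfe2l2a went in opposite directions, so it has no single value. Oxidative phosphorylation genes were lower in 30 and higher in 0 of 48 (camera adjusted p = 3.45e-05, adjusted p = 0.646 with an estimated correlation). Examples were cox6a2 (-1.80 ± 0.18), cox8a (-1.11 ± 0.17), cox7c (-0.56 ± 0.08) and ndufv2 (-0.55 ± 0.09), of which the call of cox7c was lost with quantile scaling. Lysosome and autophagy genes were higher in 16 and lower in 11 of 35 (camera adjusted p = 0.485; median 0.22, mean -0.09). The genes ctsd (0.98 ± 0.09), nbr1a (0.95 ± 0.10) and wipi2 (0.78 ± 0.09) rose, and ctsla (-1.44 ± 0.16) fell.

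Oocyte and yolk genes were lower in 21 and higher in 1 of 24 (camera adjusted p = 2.14e-04, adjusted p = 0.646 with an estimated correlation). The germ cell gene nanos3 (-4.71 ± 0.87), the gonadal gene gsdf (-2.64 ± 0.18) and h1-10 (-0.85 ± 0.14) fell. The meiotic gene sycp1 (1.08 ± 0.26) rose. Of these nanos3 was well above background on 2 mutant arrays and sycp1 on 2 sibling and 3 mutant arrays. The value of nanos3 was -5.50 without mutant replicate 1 and -4.04 without mutant replicate 4. The list's mean, relative to the 8 arrays, lay between 1.26 and 2.11 in the sibling pools and between -4.89 and 0.38 in the mutant pools, lowest in mutant replicate 4. Cell division genes, some of which oocytes store in quantity, were lower in 22 and higher in 0 of 34 (camera adjusted p = 1.47e-05, adjusted p = 0.646 with an estimated correlation). Examples were ccnb2 (-3.79 ± 0.58), ccnb1 (-3.43 ± 0.58), aurka (-2.58 ± 0.34) and stmn1a (-1.16 ± 0.20).

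**Figure D3:**
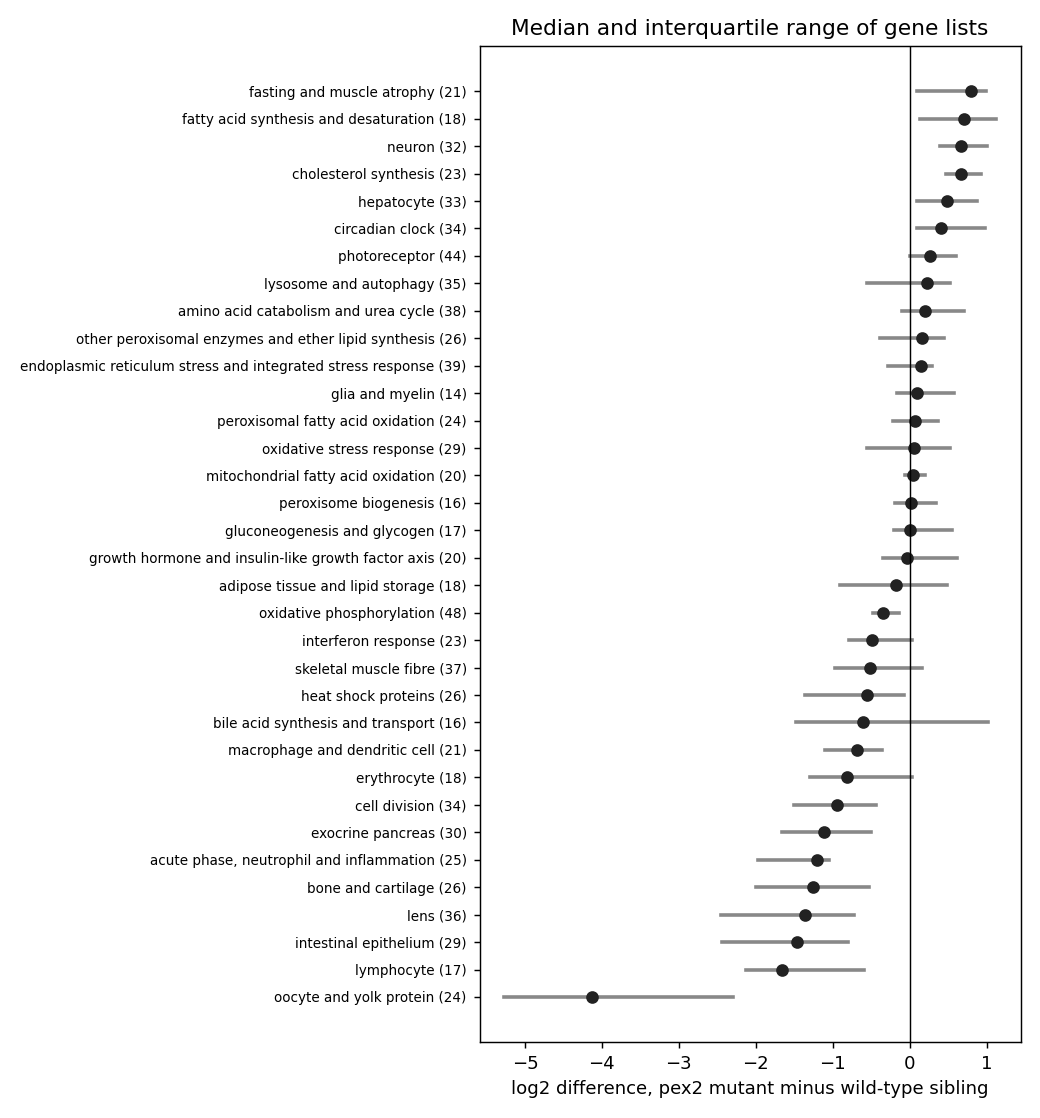
Median log2 difference, mutant minus sibling, of each of 34 gene lists, with bars for the interquartile range of their genes and the number measured in brackets. The oocyte list lies lowest, at -4.13, and the neuron list is among the highest, at 0.67.

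Tested against all other genes, 17 of the 34 lists passed with a preset correlation, 5 higher and 12 lower, and 0 with a correlation that camera estimated, where the lowest adjusted p was 0.468 and 2 lists had an unadjusted p under 0.05. With the preset correlation, 10 of the 35 ways to split the 8 arrays into 4 and 4, the real one included, called at least 17 lists, and the highest other count was 22. The counts of genes within lists rest on the test of each gene.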

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

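In 414 groups of 4 pools tested for a pool far from the other 3, over 170 named genes, 34 lists and 3 array measures, 20 stood apart, where chance gives about 20.7. Of these, 11 were in mutant pools, 2 of them in mutant replicate 4. Values of genes are log2 intensity minus the 75th percentile, and those of lists are relative to the mean over the 8 arrays.

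Among gene lists, mutant replicate 4 was low for skeletal muscle fibre, at -1.32 against -0.05 to 0.17 in the other mutant pools, and for the interferon response, at -0.34 against -0.11 to -0.09. Mutant replicate 2 was low for mitochondrial fatty acid oxidation, at -0.30 against 0.12 to 0.20, and the gene eci1 of that list at 0.88 against 1.51 to 1.57. Sibling replicate 1 was low for the exocrine pancreas, at 0.36 against 0.74 to 0.81, and for the elastase cela1.5, at -0.42 against 0.59 to 0.73. Sibling replicate 3 was high for the oxidative stress response, at 0.19 against -0.01 to 0.02.

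Mutant replicate 1 was low for ggact.1, at -3.45 against -1.88 to -1.67, for ggact.2, at -4.01 against -2.37 to -2.10, and for h1-10, at -1.29 against -0.94 to -0.91. It was high for psmb8a, at -3.40 against -4.03 to -3.95, and for asl, at 0.06 against -0.19 to -0.14. Mutant replicate 2 was low for pex14, at 0.77 against 0.92 to 0.93, and for hmox1b, at -0.50 against -0.29 to -0.24. Sibling replicate 1 was low for igf2b, at 0.70 against 0.95 to 0.97, and for gucy2d, at -0.11 against 0.13 to 0.17. Sibling replicate 2 was low for gsdf, at 1.12 against 1.69 to 1.72, and high for crygn1, at 4.28 against 3.87 to 3.91. Sibling replicate 4 was low for igf1rb, at -0.91 against -0.60 to -0.53, and high for il7r, at -2.95 against -3.17 to -3.14.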

How the results depend on the processing

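The permutation of arrays for the gene lists was chosen after seeing the data, and all other alternatives before. The count of genes past an adjusted p of 0.05 lay between 8715 and 10308 with 1 array left out, and 6415 passed against a 1.2-fold change, a test that asks for more. The count with at least a 2-fold change was 1612 with normexp and between 3129 and 3434 with 1 array left out. The share of called genes that were higher was 51.8%, and it was 60.0% with normexp, 54.6% with quantile and 52.9% with median scaling, 54.0% with no filter on dim probes, 55.2% with probes above background on all 8 arrays, and between 51.3% and 53.2% with 1 array left out. The median log2 difference of all probes moved from 0.11 to 0.19 with normexp, 0.14 with quantile, 0.12 with median scaling, 0.22 with no filter on dim probes and 0.15 with probes above background on all 8 arrays. The cause of these shifts was not tested. Over the 17264 named genes alone the median was 0.01 in the main fit, and also 0.01 with the mean of all probes of a gene. Probes without a gene name had a median of 0.30 in the main fit.

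Between 16 and 20 lists passed with 1 array left out, 33 in fry's mixed test, 0 with an estimated correlation, and 0 when the arrays were permuted. In that exact test 19 of 34 lists reached the smallest p the design allows, 0.0286, with a smallest adjusted p of 0.0511. No list could pass unless more than 19 reached that smallest p, so the 0 does not speak against any single list. The interferon response had an unadjusted p of 0.457 and heat shock proteins 0.0571 in this exact test. The mean log2 difference of peroxisomal fatty acid oxidation was 0.09 with normexp, 0.00 with quantile scaling, 0.02 with probes above background on all arrays, 0.03 with the mean of all probes, and between -0.08 and 0.07 with 1 array left out. That of gluconeogenesis and glycogen was -0.01 with normexp and between -0.14 and 0.11 with 1 array left out, and that of peroxisome biogenesis -0.01 with no filter. None of these 3 passed with camera in any setting. With normexp, ddo was 0.06 and igf1 0.25, neither past the threshold. Without mutant replicate 3, another probe of nfe2l2a was the brightest, at -0.38, and with the other arrays left out it reached 0.99.

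Replicate numbers did not pair the pools throughout: deviations of same-numbered pools correlated at 0.18, 0.098, -0.024 and -0.025. Replicates 2, 3 and 4 each correlated more with another number, and replicate 1 most with its own (0.18 against -0.032). The replicate number was also the column on the slide, so the replicate block was a slide-column block too. With the replicate block 9424 genes passed, 4894 higher, with 17 lists, the interferon response being lost (adjusted p 0.0572) and erythrocytes gained (adjusted p 0.0291), and the calls of pex26 and nudt12 lost. With the slide row as a block 9665 passed. Dim signal limits values of genes at background in 1 genotype, and no pex2 value could be computed in any setting.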

Other observations

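Several groups of genes, some with members in the lists, also moved. They were picked after their values were seen. Of 19 keratin genes, which build the skin and other epithelia, 17 were lower and 0 higher (median -1.09), with krt15 (-2.12 ± 0.14) and krt1-19d (-2.52 ± 0.19). Thyroglobulin, the precursor of thyroid hormone, fell (-3.02 ± 0.16, adjusted p = 3.90e-05), as did the mineralisation genes scpp1 (-2.31 ± 0.15) and scpp7 (-5.72 ± 0.94) and the gut hormone insl5a (-4.11 ± 0.28). The appetite peptide agrp (1.78 ± 0.22) rose. Of 39 gamma crystallins, the family of the lens genes named above, 23 were lower, 0 higher and 16 did not pass (median -1.05). All 20 zona pellucida genes were lower (median -5.41). The clone-named gene zgc:173517 was not well above background on any sibling array and was at least 9.99-fold higher in the mutants (adjusted p = 9.45e-06).

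Globins of different stages moved apart. The adult globins hbba1 (-4.55 ± 1.21) and hbaa1 (-4.04 ± 1.15) were lower, while of 7 embryonic globins hbae3 (3.98 ± 0.93), hbbe1.2 (1.90 ± 0.57) and hbbe1.1 (1.88 ± 0.59) were higher, hbae4 (-1.19 ± 0.23) lower and 3 did not pass. Similar globin probes may read each other's RNA. The tests of this pattern, of the oocyte genes, of the neuron genes and of the genes nearest pex2 were chosen after the result was seen, and the splits of the arrays and the test of genes found in mutants alone before. Embryonic minus adult globins was 1.75 and 3.61 in mutant replicates 2 and 4, and -2.48 and -2.88 in mutant replicates 1 and 3. It ranged from -5.75 to -3.95 in the sibling pools, highest in sibling replicate 1. All 4 mutant pools lay above every sibling pool, so the pattern was not in 1 pool alone. It was much larger in mutant replicates 2 and 4 than in 1 and 3. Fewer erythrocytes as the whole cause would lower other erythrocyte genes by about as much as the adult globins (median -4.29), if erythrocytes alone held their RNA. The 12 such genes of the list fixed beforehand had a median of -0.93 (interquartile range -1.21 to -0.40), with 8 lower. Whether other tissues of the whole body hold RNA of these genes was not tested. If erythrocytes alone held that RNA, these 12 genes, the lowest at -2.32, argue against fewer erythrocytes as the whole of the adult globins' fall. Fewer erythrocytes stay open as a part of it, and as the whole if other tissues hold that RNA. A delay in the change from embryonic to adult blood may underlie the globin pattern, as a hypothesis that no age series was at hand to test.

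The oocyte list had a mean of -3.51, and mutant replicate 4 lay lowest. Replicate 4 was a part and not the whole of it, since without it the mean moved to -2.47 (camera adjusted p = 6.26e-05). Over all settings the mean lay between -4.22 and -2.23, the latter on probes above background on all 8 arrays, and the adjusted p between 5.62e-06 and 0.646. Fewer or less mature oocytes, which were not tested, may account for the fall, the lower brightness of the mutant arrays stays open as a part of it, and the sex and gonad stage of the larvae, not given in the sources used here, stay open beside genotype.

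Neuron genes were higher, with a mean of 0.67. A larger share of nervous tissue would raise neuron and glia genes alike. Neuron minus glia was 0.50 higher in the mutants (exact permutation p = 0.0286, n = 4). The glia list was also higher, with a mean of 0.16 (camera adjusted p = 0.749). Against all genes the glia list was 0.28 higher (exact permutation p = 0.0286, n = 4) and the neuron list 0.78. The glia genes went both ways (median 0.10, interquartile range -0.16 to 0.57). A larger share and a change in neurons therefore cannot be told apart, and genotype stays open beside both.

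The real split was set against all other splits of the arrays. Every other split put both genotypes in each group, which widens the spread within groups and lowers the count of genes called. The rank of the real split for genes, 1 in 35 and the best possible, therefore cannot by itself exclude chance. For lists chance stays open. Of the 35 splits of the 8 arrays, 1, the real one, gave as many as 9951 genes, and 1 as many as 3364 with at least a 2-fold change, the highest other count being 0 for both. As many as 17 lists were given by 10 of the 35 splits, with 22 the highest other. A haplotype linked to pex2 was tested as a hypothesis. Of the 200 tested genes nearest pex2, 18.5% had at least a 2-fold change, against 19.5% of other genes (odds ratio 0.937, 95% interval 0.636 to 1.35, Fisher exact p = 0.788). Of 32 genes well above background in all mutant pools and no sibling pool, 0 lay on the chromosome of pex2, with 0.89 expected, which is too few to tell (odds ratio 0, upper limit 4.30).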
